A study of Equus caballus with 23 samples.

How the data were processed

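RNA was sequenced from gluteus medius biopsies of Arabian horses at 3 time points of race training, in 23 libraries. Per the labels, sequencing used 50 cycles with 6 technical repetitions, and how the repetitions were pooled is not given in the sources used here. The submitters' notes name FastQC, STAR, RSEM and DESeq2 without versions. The deposited gene and transcript tables hold expected counts estimated by RSEM, which are whole numbers in the files, for 26991 genes and 29196 transcripts. The authors also deposited comparison tables with the log2 fold change, its standard error, the p-value and the adjusted p-value from DESeq2. The same deposited tables give the mean normalized count of each gene or transcript. The genome build is not given in the sources used here, and gene coordinates and symbols were taken from the authors' tables, which annotate 9628 identifiers, 8842 of them with a symbol. The authors' tables name the groups by letters, which were assigned to time points by the mean normalized count.

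Total counts ranged from 12185608 to 23641809 per library, and the counts carry counting error on top of the spread between libraries. Of all genes, 6643 had no count in any library. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 11545 genes with 99.93% of all counts and 12334 transcripts. Counts were scaled by TMM and fitted in 1 model of the 3 time points with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3. Each comparison of 2 time points was a contrast of this fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Log2 CPM values used a prior count of 2, and CPM values used TMM-scaled library sizes. The sexes were compared in an additive model with time point, and by interaction terms.

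Gene lists and cell type marker lists were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, except those named below. The lists covered slow fibre and fast fibre contractile genes, nuclear oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, fatty acid uptake and oxidation, glycolysis and glycogen, exercise response regulators, immediate early genes, heat shock proteins and chaperones, growth and atrophy, calcium handling and excitation, extracellular matrix, angiogenesis and hypoxia, the circadian clock, myogenic and regeneration genes, inflammation, the ubiquitin proteasome system and cytosolic ribosomal proteins. The marker lists covered adipocytes, endothelial cells, smooth muscle cells and pericytes, fibroblasts, macrophages, neutrophils, lymphocytes, erythroid cells, Schwann cells and nerve, skin, and tendon and cartilage. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (two-sided) with a preset correlation of 0.01 and again with an estimated correlation. In each comparison the text names genes from the 8 largest rises and 8 largest falls among called genes with a symbol and a mean log2 CPM of at least 2, from up to 2 called members of each list with the smallest p, and from a fixed panel (MYH1, MYH2, MYH7, PPARGC1A, PDK4, MSTN, PGAM2, LDHA, CKM and COL1A1). MYH1 and MSTN had no tested identifier under that symbol.

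Library-level values were compared by exact two-sided permutation tests, adjusted over 48 comparisons. The alternatives were DESeq2-type median ratio factors, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, sex as a covariate, 1 surrogate variable from sva 3.50.0, only the 2 time points compared in the fit, a fit that was not robust, and leaving out each library in turn. Further alternatives, added after seeing the data, left out libraries m3 and m12, used a slow minus fast fibre score as a covariate, removed the trend on gene span in each library, and thinned the counts to the smallest total of 12185608. The score was the mean log2 CPM of the slow fibre list minus that of the fast fibre list. The test was checked on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold. It recovered 84% and 97% of them for T1 minus T0, 93% and 100% for T2 minus T1, and 74% and 96% for T2 minus T0, with 10, 5 and 9 false calls. The changed genes were taken from those with higher counts, and genes were simulated independently without an outlying library. These values therefore do not cover weakly expressed genes or genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No reference genome was used, and read-level data were not analysed here.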

Results

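Gene expression was measured by RNA sequencing in needle biopsies of the gluteus medius, a large hindquarter muscle, from Arabian horses. The 23 libraries fell into 3 time points of flat race training. T0 held 5 libraries of untrained horses aged 2.5 years (3 male and 2 female), T1 held 8 libraries of horses aged 3 years after the intense gallop phase that precedes the racing season (4 male and 4 female), and T2 held 10 libraries of horses aged 3 years at the end of the season (7 male and 3 female). The labels number the libraries from m1 to m23 without repeating a number across time points and do not say whether a horse was sampled more than once, so all libraries were compared as unpaired samples. Age was 2.5 years only in T0 and could not be separated from training status in comparisons with T0. The p-values measure the spread between these libraries.

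Total counts per library ranged from 12604125 to 17477172 in T0, from 15417737 to 23641809 in T1 and from 12185608 to 19804694 in T2. Transcripts of the mitochondrial genome made up a large part of each library, and COX1, the mitochondrially encoded cytochrome c oxidase subunit, alone took 16.3% of all counts. Mitochondrially encoded genes took 42.9% ± 7.77 of counts in T0 (SD, n = 5), 53% ± 3.99 in T1 (SD, n = 8) and 48.1% ± 2.87 in T2 (SD, n = 10). The share was lower in T2 than in T1 by an exact two-sided permutation test (p = 0.00887, adjusted p = 0.0473 over 48 comparisons of library values), whereas the difference between T1 and T0 did not pass (exact permutation p = 0.0124, adjusted p = 0.0541). T1 libraries were deeper than T0 libraries (exact permutation p = 0.00699, adjusted p = 0.0419) and T2 libraries (exact permutation p = 0.00251, adjusted p = 0.0191). No library pair held identical values, and pairwise correlations of log2 CPM lay between 0.9091 and 0.9796.

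The comparison of T1 with T0 asked how muscle after the gallop phase differed from untrained muscle. Of 15 slow fibre contractile genes, 13 rose and 0 fell in T1, with a median log2 fold change of 1.98, and 15 rose when adjusted over the list alone (adjusted p = 0.0635 with an estimated correlation). MYL3, the slow ventricular-type myosin light chain, rose from 519 ± 297 CPM in T0 (SD, n = 5) to 2350 ± 1670 CPM in T1 (SD, n = 8), a log2 fold change of 2.18 ± 0.41 (SE, adjusted p = 0.00332). ANKRD2, a stretch-responsive ankyrin repeat protein of slow fibres, rose by 2.91 ± 0.50 (adjusted p = 0.00204). MYH7, which encodes the slow myosin heavy chain (ENSECAG00000019844, chromosome 1, 161506573 to 161527244), rose from 8250 ± 6120 to 30000 ± 15600 CPM, a log2 fold change of 1.86 ± 0.48 (adjusted p = 0.0197). Of 14 fast fibre contractile genes, 5 fell, 0 rose and 9 did not pass, and 11 fell when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). The mean log2 CPM of the fast list was 10.5 ± 1.29 in T1 (SD, n = 8) and 11.9 ± 0.472 in T0 (SD, n = 5), which did not pass correction (exact permutation p = 0.0218, adjusted p = 0.0842). The count of 5 became 2 without T0 library m10, 3 without T1 library m11 or T0 library m12, 1 without T0 library m13 and 8 without T1 library m3. It was 2 with only the 2 time points in the fit and 3 without the filter on low counts.

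Among fast fibre genes, a myosin heavy chain gene that the authors' tables name MYH2 (ENSECAG00000022909, chromosome 11, 52973970 to 52998897) fell from 22400 ± 12000 CPM in T0 to 2090 ± 1790 CPM in T1, a log2 fold change of -3.42 ± 0.64 (SE, adjusted p = 0.00364). The neighbouring gene carrying the same symbol (ENSECAG00000024667, chromosome 11, 53001919 to 53027479) had 16600 ± 5610 CPM in T0 and 18700 ± 9380 CPM in T1, with a log2 fold change of 0.17 ± 0.51 that did not pass (adjusted p = 0.892). These neighbouring myosin genes are close paralogs, so the division of short reads between them is uncertain. Either id may correspond to another fast myosin heavy chain than MYH2. ACTN3, the fast fibre alpha-actinin, fell by 1.67 on the log2 scale (SE 0.42, adjusted p = 0.018). Its call ended without T0 library m13 (log2 fold change -1.43, adjusted p = 0.0601) and with only the 2 time points in the fit (-1.67, adjusted p = 0.0598). The call of MYH7 ended without T0 library m8, m10 or m13, with an adjusted p of up to 0.0702 and a log2 fold change of 1.69 without m10. MYOZ2, a slow fibre calcineurin-binding protein of the Z-disc, rose by 3.49 ± 0.85 (adjusted p = 0.0177). Its call ended at an adjusted p of 0.0505 without T0 library m10 (log2 fold change 3.52) and of 0.0834 with only the 2 time points in the fit (3.49). T1 library m3 stood apart, with a mean log2 CPM of slow minus fast fibre genes of 3.36 against 0.13 for the next T1 library.

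**Figure D1:**
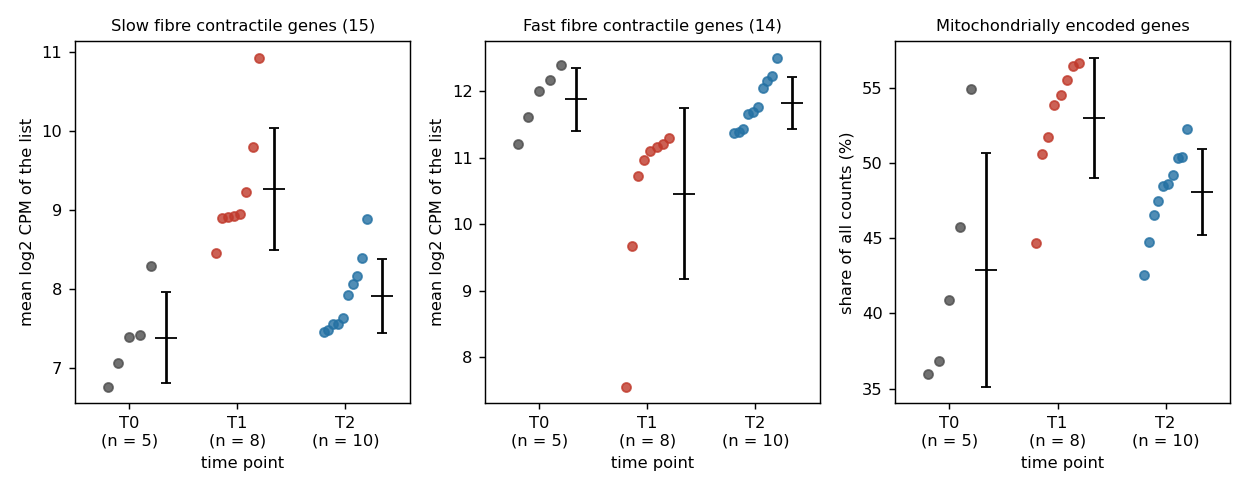
Mean log2 CPM of the slow and fast fibre contractile lists and the percentage of counts from mitochondrially encoded genes, with 1 point per library at each time point, and the mean ± SD as a bar with whiskers. The slow list averages 7.39 in T0, 9.26 in T1 and 7.92 in T2, and T1 library m3 is the lowest point of the fast list at 7.56.

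Of 25 genes of fatty acid uptake and oxidation, 14 rose, 0 fell and 11 did not pass in T1 (19 rose when adjusted over the list alone, adjusted p = 0.0635 with an estimated correlation). ACADS, the short-chain acyl-CoA dehydrogenase, rose by 0.78 ± 0.15 (SE, adjusted p = 0.00316), and ETFDH, which passes electrons from fatty acid oxidation to ubiquinone, rose by 0.65 ± 0.12 (adjusted p = 0.00343). Of 20 tricarboxylic acid cycle genes, 8 rose and 0 fell, and 17 rose when adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). PDHA1, the pyruvate dehydrogenase subunit, rose by 0.55 ± 0.13 (adjusted p = 0.00972), and SDHB, a subunit of succinate dehydrogenase, by 0.67 ± 0.15 (adjusted p = 0.00731). The count of 8 was 2 without T0 library m10 and 5 without T0 library m13. It was 13 with 1 surrogate variable and 18 in limma voom with sample weights. Of 58 nuclear oxidative phosphorylation genes, 9 rose and 0 fell, with a median log2 fold change of 0.43. When adjusted over the list alone 27 rose (adjusted p = 0.225 with an estimated correlation). That count of 9 was 1 without T0 library m10, 2 without T0 library m9 or m13, 4 without T1 library m1, m5 or m7, 5 without T1 library m2, 15 without T1 library m11 and 17 without T0 library m12. It was 4 with only the 2 time points in the fit, 14 with the trend on gene span removed, 15 with sex as a covariate, 19 with 1 surrogate variable, 22 in DESeq2 and 28 in limma voom with sample weights. None of 12 mitochondrially encoded genes passed over all genes tested (median 0.55), and 9 rose when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation).

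Of 30 glycolysis and glycogen genes, 17 fell, 2 rose and 11 did not pass in T1, with 19 fallen and 3 risen when adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). PGAM2, the muscle phosphoglycerate mutase, fell from 1640 ± 304 CPM in T0 (SD, n = 5) to 787 ± 245 CPM in T1 (SD, n = 8), a log2 fold change of -1.06 ± 0.23 (SE, adjusted p = 0.00731). PPP1R3A, the glycogen-targeting phosphatase subunit, fell by 0.89 on the log2 scale (SE 0.19, adjusted p = 0.00575). The lactate dehydrogenase subunits moved apart: LDHA, typical of glycolytic muscle, fell by 1.30 on the log2 scale (SE 0.33, adjusted p = 0.0175), and LDHB, typical of oxidative muscle, rose by 2.32 ± 0.44 (adjusted p = 0.00367). Without T0 library m10, LDHA had a log2 fold change of -1.12 and an adjusted p of 0.0717. With only the 2 time points in the fit it had -1.30 and 0.0562. The count of 17 was 5 without T0 library m10, 6 without T0 library m13, and 11 without T1 library m11 or with only the 2 time points in the fit. PPARGC1A (0.25 ± 0.50, adjusted p = 0.83), PDK4 (2.38 ± 1.51, adjusted p = 0.389) and CKM (0.48 ± 0.27, adjusted p = 0.312) did not pass.

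Other genes with large changes in T1 included SLC16A7, a monocarboxylate transporter (2.34 ± 0.46, adjusted p = 0.00444), S100A1, a calcium-binding regulator of contraction (2.08 ± 0.50, adjusted p = 0.0161, and 0.0575 with only the 2 time points in the fit), and TYRP1, known as a melanosome protein (3.25 ± 0.65, adjusted p = 0.00512). MICAL2, an actin-oxidizing enzyme, had a log2 fold change of -3.21 ± 0.60 (adjusted p = 0.00378), LMOD1, an actin nucleator of smooth muscle, -2.31 ± 0.40 (adjusted p = 0.00228), and SUSD4, a complement regulator, -2.08 ± 0.31 (adjusted p = 0.00108). Of 22 heat shock and chaperone genes 3 rose and 0 fell (4 when adjusted over the list alone, adjusted p = 0.225 with an estimated correlation), including CRYAB by 1.23 ± 0.22 (adjusted p = 0.00246) and the mitochondrial chaperonin HSPD1 by 0.62 ± 0.12 (adjusted p = 0.00381).

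Of 42 extracellular matrix genes, 7 fell in T1, 0 rose and 35 did not pass (14 fell when adjusted over the list alone; adjusted p = 0.344 with an estimated correlation). TIMP2, a metalloproteinase inhibitor, fell by 0.64 on the log2 scale (SE 0.13, adjusted p = 0.00391) and the membrane metalloproteinase MMP14 by 1.19 (SE 0.25, adjusted p = 0.00518). COL1A1 had a log2 fold change of -1.33 ± 0.47 that did not pass (adjusted p = 0.0866). The count of 7 was 4 without T1 library m3, m4, m5, m7 or m11 or T0 library m8, 3 without T0 library m9 or m10, and 15 without T0 library m12. It was 4 without the filter on low counts and 18 in limma voom with sample weights. Of 10 fibroblast markers, 2 fell (8 when adjusted over the list alone, adjusted p = 0.244 with an estimated correlation). These, DCN and COL3A1, lost their calls in 8 and 9 of 23 fits that each left out 1 library. The fit without T0 library m10 gave the highest adjusted p (0.193 for DCN, with a log2 fold change of -0.56, and 0.142 for COL3A1, with -1.19). Both calls also ended without the filter on low counts (adjusted p = 0.0662 for DCN and 0.0725 for COL3A1) and with only the 2 time points in the fit (0.067 and 0.0724). The mean log2 CPM of fibroblast markers was 3.27 ± 0.352 in T1 (SD, n = 8) and 4.05 ± 0.851 in T0 (SD, n = 5), an exact permutation p of 0.0373 that did not pass correction (adjusted p = 0.0995).

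In total, 798 of 11545 tested genes changed between T1 and T0, of which 412 were higher and 386 lower, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Without T0 library m10 the count was 346, and with sample weights in limma voom it was 1512. With the slow minus fast fibre score of each library as a covariate it was 1. The score ran from -5.63 (m13) to -3.79 (m8) in T0 and from -2.64 (m4) to 3.36 (m3) in T1, without overlap. A covariate that separates the groups takes up much of their difference, so this fit cannot tell whether the fibre mix accounts for the changes. With that covariate LDHA had a log2 fold change of 0.11, and MYOZ2 and ACTN3 had -0.03 and 0.04, although both belong to the lists that make up the score, which shrinks their change by construction. In the camera test with a preset correlation 12 lists moved, and none did with an estimated correlation. Among the lists not given above, inflammation had adjusted p = 0.371 with an estimated correlation and cytosolic ribosomal proteins adjusted p = 0.766 with an estimated correlation.

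The comparison of T2 with T1 asked how muscle changed between the start and the end of the racing season. Of 15 slow fibre contractile genes, 12 fell, 0 rose and 3 did not pass in T2, with a median log2 fold change of -1.49 (13 fell when adjusted over the list alone, adjusted p = 0.751 with an estimated correlation). MYH7 fell from 30000 ± 15600 CPM in T1 (SD, n = 8) to 8450 ± 6650 CPM in T2 (SD, n = 10), a log2 fold change of -1.83 ± 0.37 (SE, adjusted p = 0.000946). PLN, the phospholamban brake on the slow fibre calcium pump, had a log2 fold change of -1.67 ± 0.28 (adjusted p = 0.000213), the pump gene ATP2A2 itself -1.46 ± 0.26 (adjusted p = 0.000293) and MYOZ2 -3.13 ± 0.63 (adjusted p = 0.00117). Of 14 fast fibre contractile genes, 11 rose, 0 fell and 3 did not pass (12 rose when adjusted over the list alone and 7 without the filter on low counts, adjusted p = 0.751 with an estimated correlation). ENSECAG00000022909, named MYH2 in the authors' tables though it may be another fast myosin heavy chain, rose from 2090 ± 1790 to 15000 ± 7960 CPM, a log2 fold change of 2.84 ± 0.58 (adjusted p = 0.00112). ENSECAG00000024667 had a log2 fold change of 0.00 ± 0.42 (adjusted p = 0.998). MYL1, the fast alkali light chain, rose by 1.38 ± 0.32 (adjusted p = 0.00294).

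Of 30 glycolysis and glycogen genes, 20 rose, 3 fell and 7 did not pass in T2 relative to T1 (21 and 4 when adjusted over the list alone, adjusted p = 0.751 with an estimated correlation). PGAM2 rose by 1.21 ± 0.20 (SE, adjusted p = 0.000164), ENO3, the muscle enolase, by 1.20 ± 0.20 (adjusted p = 0.000179) and LDHA by 1.26 ± 0.28 (adjusted p = 0.00221). The 3 that fell, named after their values were seen, were LDHB (-1.59), PPP1R3C (-0.76) and GBE1 (-0.69). Of 25 fatty acid genes, 14 fell, 1 rose and 10 did not pass, the same counts as when adjusted over the list alone (adjusted p = 0.751 with an estimated correlation), and 9 fell without T1 library m11. ETFDH had a log2 fold change of -0.53 ± 0.10 (adjusted p = 0.000518) and ACADS -0.55 ± 0.12 (adjusted p = 0.00134). The member that rose was UCP3, a mitochondrial uncoupling protein (1.86 ± 0.49, adjusted p = 0.00826). It had 33.8 ± 11.9 CPM in T0 (SD, n = 5), 16.6 ± 8.04 in T1 (SD, n = 8) and 60.2 ± 64.3 in T2 (SD, n = 10). In T2, libraries m14 (163.5 CPM) and m21 (196.9 CPM) stood far above the next, m19 (38.71 CPM), and no fit left out both. Of 20 tricarboxylic acid cycle genes, 3 fell and 0 rose (2 when adjusted over the list alone), among them OGDH, a subunit of oxoglutarate dehydrogenase (-0.55 ± 0.13, adjusted p = 0.00239), and CS, citrate synthase (-0.39 ± 0.11, adjusted p = 0.0101). The count of 3 was 5 in DESeq2 or with 1 surrogate variable and 6 in limma voom with sample weights. Of 58 nuclear oxidative phosphorylation genes, 5 rose and 0 fell (0 when adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0303; adjusted p = 0.824 with an estimated correlation). That count of 5 was 19 without T1 library m3, 10 without T2 library m15, 8 without T2 library m19 and 3 without T2 library m21. It was 2 without T1 library m2, m4 or m6 or T2 library m18, and 1 without T1 library m5, m7 or m11 or T2 library m14, m16, m17 or m22. Other fits gave 9 in DESeq2, 22 in limma voom with sample weights, 2 without the filter on low counts or with sex as a covariate, and 3 with the trend on gene span removed. With the slow minus fast fibre score as a covariate, 3 glycolysis genes and 19 oxidative phosphorylation genes rose and 2 fatty acid genes fell. The score did not overlap between T1 and T2 libraries, which limits what this fit can tell. Of 12 mitochondrially encoded genes, ND5 and ND4L fell, each with a log2 fold change of -0.53.

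Of 27 exercise response regulators, 8 fell and 3 rose in T2 relative to T1 (11 and 3 when adjusted over the list alone), and the list did not move in the camera test (adjusted p = 0.0582). PPARA, a nuclear receptor that drives fatty acid oxidation, went from 22.1 ± 5.43 CPM in T1 (SD, n = 8) to 6.82 ± 2.97 CPM in T2 (SD, n = 10), a log2 fold change of -1.69 ± 0.22 (SE, adjusted p = 1.72e-05). ESRRB, an estrogen-related receptor, had a log2 fold change of -1.56 ± 0.21 (adjusted p = 1.54e-05). PPARGC1A had a log2 fold change of 0.18 ± 0.41 that did not pass (adjusted p = 0.781). Of 17 circadian clock genes, 5 fell and 3 rose (6 and 3 when adjusted over the list alone), including the clock output factor TEF (-0.65 ± 0.14, adjusted p = 0.00134). Of 22 growth and atrophy genes, 6 fell and 3 rose (6 and 4 when adjusted over the list alone), including the growth factor receptor IGF1R (-0.91 ± 0.17, adjusted p = 4e-04) and the transforming growth factor mediator SMAD3 (-0.86 ± 0.18, adjusted p = 0.00109). The count of 3 risen was 1 without T1 library m7 or m11 or T2 library m14 or m21, or without the filter on low counts.

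Of 33 proteasome genes, 10 rose in T2 relative to T1, 0 fell and 23 did not pass (17 rose when adjusted over the list alone; adjusted p = 0.751 with an estimated correlation). PSMA4 rose by 0.64 ± 0.09 (SE, adjusted p = 3.24e-05) and PSMA3 by 0.58 ± 0.12 (adjusted p = 0.000981), both subunits of the catalytic core. The count was 27 without T1 library m3 and 19 without T2 library m15. It was 23 with the slow minus fast fibre score as a covariate, 17 in DESeq2 and 26 in limma voom with sample weights. Of 25 angiogenesis and hypoxia genes, 5 fell and 1 rose (the same counts when adjusted over the list alone), including PDGFB (-0.91 ± 0.18, adjusted p = 0.000601) and ARNT (-0.47 ± 0.11, adjusted p = 0.00348). That count of 5 was 10 without T1 library m3, 3 without T1 library m11 or with the trend on gene span removed, and 11 in limma voom with sample weights. Of 30 calcium handling and excitation genes, 7 fell and 6 rose (7 and 7 when adjusted over the list alone). CACNA2D1, a calcium channel subunit, had a log2 fold change of -0.83 ± 0.13 (adjusted p = 6.8e-05), and DHRS7C, a sarcoplasmic reticulum dehydrogenase, 0.90 ± 0.15 (adjusted p = 0.000195). ACOT11, an acyl-CoA thioesterase, had -2.05 ± 0.27 (adjusted p = 2.04e-05) and XPO4, a nuclear exportin, -2.01 ± 0.27 (adjusted p = 1.89e-05), and FAM69A rose by 1.89 ± 0.27 (adjusted p = 3.61e-05).

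Between T2 and T1, ANKRD1, XIRP1, ATF3 and BTG2 had log2 fold changes of -2.17 ± 0.70, -2.19 ± 0.65, -2.46 ± 0.84 and -2.79 ± 0.91 (SE, adjusted p = 0.0263, 0.0163, 0.0334 and 0.0281). Without T1 library m6 these log2 fold changes were -0.43, -0.59, -0.39 and 0.01, and none passed. In DESeq2 with all libraries they were -0.37, -0.52, -0.32 and 0.03, and none passed. By default DESeq2 replaces outlying counts in groups as large as T1, so this fit may not be separate from leaving out m6. With sex as a covariate none passed (adjusted p = 0.217, 0.0617, 0.177 and 0.257). The calls of ANKRD1, ATF3 and BTG2 also ended with 1 surrogate variable and in limma voom with sample weights. That of ATF3 also ended without the filter on low counts or without T2 library m16, m17, m18, m19, m21 or m22. With all libraries 3 of 15 immediate early genes fell, and 0 did when adjusted over the list alone. The count of 3 became 0 without m6, 6 without T2 library m15, and 1 without T2 library m16, m17, m18, m19, m21 or m22. It became 0 with sex as a covariate or 1 surrogate variable, and 1 in DESeq2, in limma voom with sample weights or without the filter on low counts. Myogenic and regeneration genes fell in 5 and rose in 1 of 16, the same counts as when adjusted over the list alone, and fell in 3 without m6, in DESeq2 or with sex as a covariate. This list includes ANKRD1 and XIRP1, as well as CHRNA1, the muscle acetylcholine receptor subunit (-1.47 ± 0.26, adjusted p = 0.000363).

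In total, 3188 of 11545 genes changed between T2 and T1, with 1450 higher and 1738 lower, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Among changes of at least 2-fold, 135 were higher and 397 lower. Across genes, the T2 minus T1 change went down with the length of the gene on the chromosome (Spearman rho = -0.23 over 9628 genes, which are not independent replicates). With a preset correlation 7 lists moved in the camera test, and none did with an estimated correlation. Among the lists not given above, cytosolic ribosomal proteins had adjusted p = 0.824 with an estimated correlation.

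The comparison of T2 with T0 asked what differed from untrained muscle at the end of the season. Most nuclear genes of the respiratory chain rose, as did 16 of 33 proteasome genes, while 1 slow fibre gene and no fast fibre gene passed the test. Neither the respiratory chain nor the proteasome list passed a test that allows for correlation between its genes (adjusted p = 0.403 with an estimated correlation for both). Of 58 nuclear oxidative phosphorylation genes, 45 rose and 0 fell, with a median log2 fold change of 0.55 (52 rose when adjusted over the list alone). The median was already 0.43 in T1 minus T0, where 9 were called, so the counts of calls differ more than the size of the change. COX5A, a cytochrome c oxidase subunit, rose from 300 ± 45 CPM in T0 (SD, n = 5) to 487 ± 83.4 CPM in T2 (SD, n = 10), a log2 fold change of 0.70 ± 0.15 (SE, adjusted p = 0.00545). NDUFV2, a subunit of complex I, rose by 0.63 ± 0.14 (adjusted p = 0.006). The count of 45 was 22 without T0 library m9, 26 without T0 library m10 and 17 without T0 library m13. Of 15 slow fibre genes 1 rose, ANKRD2 (1.32 ± 0.45, adjusted p = 0.0476), and none passed when adjusted over the list alone. The median of the slow fibre list was 0.50, and it moved up in the camera test with a preset correlation (adjusted p = 0.00927; adjusted p = 0.691 with an estimated correlation). The call of ANKRD2 ended in 17 of 23 fits that each left out 1 library, with log2 fold changes from 0.96 to 1.44. It also ended without the filter on low counts (adjusted p = 0.0804), with 1 surrogate variable (0.11) and with the trend on gene span removed (0.0587). None of 14 fast fibre genes passed on either adjustment (median 0.02). MYH7 had a log2 fold change of 0.04 ± 0.43 (adjusted p = 0.966), ENSECAG00000022909, named MYH2 by the authors, one of -0.58 ± 0.60 (adjusted p = 0.527) and LDHA one of -0.04 ± 0.32 (adjusted p = 0.943).

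Of 33 proteasome genes, 16 rose and 0 fell in T2 relative to T0 (21 rose when adjusted over the list alone). PSMB2 rose by 0.62 ± 0.13 (SE, adjusted p = 0.00487) and PSMA4 by 0.53 ± 0.11 (adjusted p = 0.00444). The count of 16 was 6 without T0 library m9 or m13, 9 without T2 library m16 or m17, 10 without T0 library m8 or T2 library m22, and 25 in limma voom with sample weights. Of 20 tricarboxylic acid cycle genes, 7 rose and 0 fell (12 when adjusted over the list alone, adjusted p = 0.403 with an estimated correlation), including IDH3A, a subunit of isocitrate dehydrogenase (0.68 ± 0.16, adjusted p = 0.00806). That count of 7 was 2 without T0 library m13, 3 without T0 library m9 or m10 or T2 library m17, and 4 without T0 library m8 or T2 library m16, m18 or m22. It was 11 without T0 library m12 and 12 without T2 library m15. Other fits gave 12 in DESeq2 and in limma voom with sample weights, and 3 with only the 2 time points in the fit. Of 22 heat shock and chaperone genes, 6 rose and 0 fell on either adjustment, when adjusted over the list alone included (adjusted p = 0.403 with an estimated correlation). CRYAB rose by 0.86 ± 0.21 (adjusted p = 0.0103) and HSPD1 by 0.63 ± 0.12 (adjusted p = 0.00285). The count of 6 was 3 without T0 library m9, 2 without T0 library m13 and 3 with the trend on gene span removed. Of 30 glycolysis and glycogen genes 1 rose, on either adjustment: UGP2, which makes the glucose donor of glycogen (0.79 ± 0.16, adjusted p = 0.00369).

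Most of the larger changes between T2 and T0 were decreases. Of changes of at least 2-fold, 304 were lower and 22 higher in T2. RNF213, a large ubiquitin ligase, had a log2 fold change of -1.72 ± 0.29 (SE, adjusted p = 0.00125), the centrosomal gene NIN -1.45 ± 0.24 (adjusted p = 0.00117), the cytokine receptor LIFR -1.43 ± 0.33 (adjusted p = 0.00754) and SH3PXD2A, an adaptor of podosomes, -1.40 ± 0.22 (adjusted p = 0.00116). Among called genes with a symbol and a mean log2 CPM of at least 2, the largest rise was that of 5_8S_rRNA, a ribosomal RNA (ENSECAG00000027377), from 10.9 ± 9.21 CPM in T0 (SD, n = 5) to 56.1 ± 31 CPM in T2 (SD, n = 10), a log2 fold change of 2.37 ± 0.76 (SE, adjusted p = 0.0399). It also rose by 1.86 ± 0.61 from T1 (adjusted p = 0.0287). Its call against T0 ended in 9 of 23 fits that each left out 1 library (without T0 library m8, m9, m10 or m12 or T2 library m14, m17, m18, m21 or m22), with an adjusted p of up to 0.0923 (log2 fold change 2.15 without m8). It also ended without the filter on low counts (adjusted p = 0.0604), with sex as a covariate (0.0518) and with 1 surrogate variable (0.0549). Its call against T1 ended in 5 (without T1 library m2, m5, m6, m7 or m11), with up to 0.0543 (1.74 without m5). LYRM7, an assembly factor of complex III, rose by 0.98 ± 0.16 (adjusted p = 0.00116). Gene length went with the direction. Across 9628 genes with coordinates, the T2 minus T0 change and the length of the gene on the chromosome had a Spearman rho of -0.30 (genes are not independent replicates), and with the genes in 4 equal groups by length the median log2 fold change was 0.14 in the shortest group and -0.17 in the longest. The longest group held 436 genes called lower and 79 called higher, against 58 and 283 in the shortest.

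Some adipocyte, extracellular matrix and smooth muscle or pericyte genes fell between T0 and T2. SCD and FASN, enzymes of fatty acid synthesis, had log2 fold changes of -2.64 ± 0.79 (SE, adjusted p = 0.0289) and -1.36 ± 0.36 (adjusted p = 0.0159), and both calls ended without T0 library m10 (-0.75 and -0.68). The call of SCD also ended without the filter on low counts (adjusted p = 0.0502), with sex as a covariate (0.059) and with 1 surrogate variable (0.0937). SCD and FASN are 2 of the 3 adipocyte markers of 9 that fell (3 when adjusted over the list alone, 1 without m10). IGFBP5 had a log2 fold change of -1.66 ± 0.42 (adjusted p = 0.0132), and -0.84 without T0 library m13, where it did not pass. Of 42 extracellular matrix genes, 6 fell and 0 rose (9 fell when adjusted over the list alone, adjusted p = 0.691 with an estimated correlation), including the laminin chain LAMC1 (-0.70 ± 0.14, adjusted p = 0.0042). That count of 6 was 3 without T0 library m9, 14 without T0 library m12, 11 without T2 library m14, 12 without T2 library m15, 15 without libraries m3 and m12 together and 23 in limma voom with sample weights. Of 11 smooth muscle and pericyte markers, 4 fell on either adjustment, when adjusted over the list alone included, with RGS5 at -0.82 ± 0.18 (adjusted p = 0.00624). That count was 1 without T0 library m8, m9, m10 or m13 or T2 library m17, 2 without T2 library m16, m18 or m22, 1 without the filter on low counts and 2 with only the 2 time points in the fit. Among 17 clock genes 3 fell and 1 rose on either adjustment, including CLOCK (-1.07 ± 0.29, adjusted p = 0.0167) and TEF (-0.74 ± 0.16, adjusted p = 0.00534).

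In total, 1851 of 11545 genes changed between T2 and T0, with 777 higher and 1074 lower, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. The count was 1075 without T0 library m9, 986 without T0 library m13 and 2947 without libraries m3 and m12 together, and limma voom with sample weights gave 2940. With a preset correlation 10 lists moved in the camera test, and none did with an estimated correlation. Among the lists not given above, the fatty acid list had adjusted p = 0.403 with an estimated correlation, and the mitochondrially encoded, cytosolic ribosomal protein and endothelial lists had adjusted p = 0.691 with an estimated correlation.

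**Figure D2:**
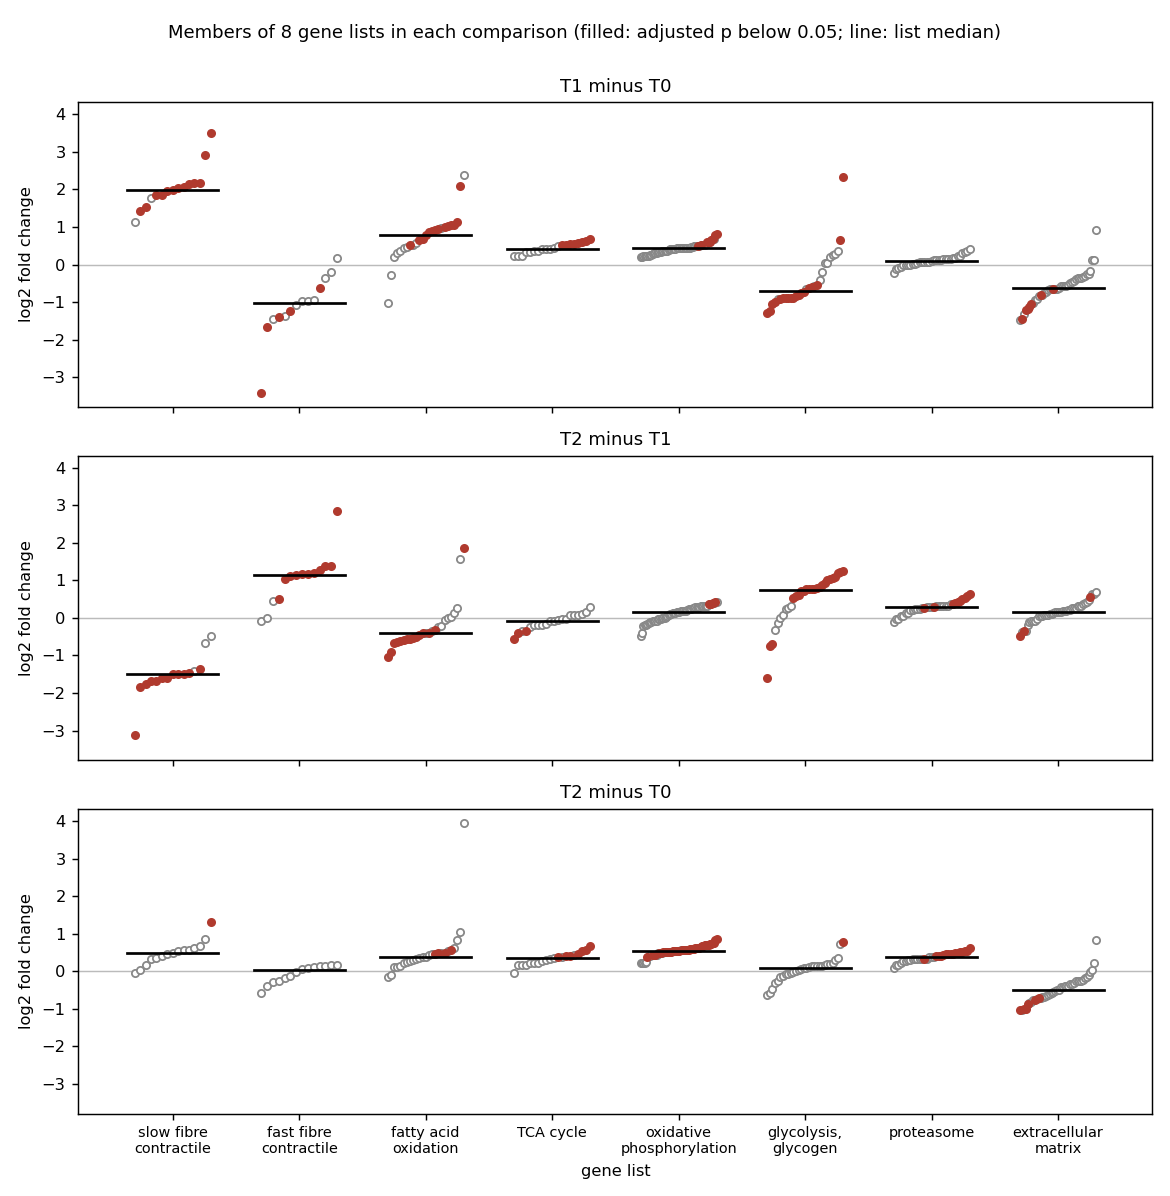
Log2 fold change of each tested member of 8 gene lists in the 3 comparisons, with filled points for members at an adjusted p below 0.05, open points for the others and a line at the list median. Slow fibre genes have a median of 1.98 in T1 minus T0, -1.49 in T2 minus T1 and 0.50 in T2 minus T0. The medians of oxidative phosphorylation genes are 0.43, 0.16 and 0.55 in the same order.

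Many of the genes that changed from T0 to T1 changed back from T1 to T2. Of the genes higher in T1 than in T0, 258 were lower in T2 than in T1, and of those lower in T1, 216 were higher in T2. None of the 474 genes called in both comparisons moved in the same direction in both. Both comparisons use the T1 libraries, which alone creates opposite changes, so the values were set against references. Independent lists of these sizes would share 62 and 48.5 genes, and 20 simulations of unchanged groups shared 0, which is no reference for the count because no gene changes in them. With different T1 libraries in each comparison (10 random divisions of T1 into parts of 4) the medians were 80.5 and 35.5 shared genes, against 8.87 and 2.96 for independent lists. The covariance of the fold changes across genes was -0.1519, against -0.0319 in the simulations, a difference of -0.12. Their Pearson r was -0.557, against -0.453 in the simulations. Genes were simulated independently of each other, whereas real genes move together, so the simulations are no full reference for either value.

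The sexes were compared within time points. No gene passed between 14 male and 9 female libraries in edgeR's quasi-likelihood test (719 genes had an unadjusted p below 0.05), and DESeq2 called 1. No difference between the sexes in the change between time points passed in edgeR, for T1 minus T0 (483 genes at an unadjusted p below 0.05, 3 called by DESeq2) or for T2 minus T1 (179 genes at an unadjusted p below 0.05, 4 called by DESeq2). KDM6A, an X-linked gene known to escape inactivation, had 9.96 CPM on average in males and 14 CPM in females, a log2 difference of -0.49 ± 0.12 (SE) that did not pass over all genes (edgeR adjusted p = 0.373).

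At transcript level, 614 of 12334 tested transcripts changed between T1 and T0, 2948 between T2 and T1 and 1525 between T2 and T0 in the same test. The authors' deposited tables of gene comparisons, which name their groups by letters only, matched these 3 contrasts by mean expression, with median differences of 0.271% to 0.411% for the matched contrast. At an adjusted p below 0.05, the authors' deposited table held 1183 genes for T1 minus T0, 3403 for T2 minus T1 and 2227 for T2 minus T0. Of the genes called in both sources, 663, 2817 and 1578 moved in the same direction, and 0 moved in opposite directions.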

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

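The tests of a single deciding library, of the fibre mix and of gene span below, of fewer other cells, and of the sex labels were chosen only after the related result was seen, and thinning of the counts was also an alternative added after seeing the data.

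Most slow fibre genes were higher in T1 than in T0 and T2, and 5 of 14 fast fibre genes were lower in T1 than in T0 and 11 lower than in T2. The tables argue against a single deciding library for the slow fibre rises in T1 minus T0, since at least 10 of 15 genes were called whichever library was left out. The fast fibre list kept a median of -0.82 (without T1 library m3) or further from 0. Its calls, however, depended on single libraries. The 5 became 8 without m3, 2 without T0 library m10, 3 without T1 library m11 or T0 library m12 and 1 without T0 library m13. The tables also argue against deeper sequencing of T1 as the reason for the calls, since thinning left 13 slow fibre and 5 fast fibre calls. The fast fibre median after thinning was -1.02, which decides nothing, since thinning hardly moves the fold changes of abundant genes. A different mix of slow and fast fibres in the biopsies, from the sampling site or from training, may account for part of the wider change: across 780 called genes outside both lists, the T1 minus T0 change and the one predicted from the fibre score within time points had a Pearson r of 0.51 (0.47 without m3; genes are not independent replicates), but for T2 minus T1 the r was 0.25 over 3165 genes (0.6 without m3) with 45.4% of signs shared (71.6% without m3). With the score as a covariate the median change went from 0.83 (median SE 0.21) to 0.48 (median SE 0.26) for T1 minus T0, where 1 gene stayed called. For T2 minus T1 it went from 0.57 to 0.59, and 1739 of 3165 genes stayed called. There the glycolysis rises went from 20 to 3 and the fatty acid falls from 14 to 2. The lowest score in T1 (-2.64, m4) lay above the highest in T0 (-3.79, m8) and in T2 (-2.78, m23), so part of the lost calls was built into this fit. Sampling and training therefore cannot be told apart, and for T2 minus T1 the prediction turns on m3.

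Of 58 nuclear oxidative phosphorylation genes, 45 were higher in T2 than in T0. The tables argue against the trend on gene span as the whole cause, since 37 of 58 genes were called after it was removed. Gene span is the length on the chromosome, not that of the transcript, so a loss of reads tied to transcript length was not tested. The list's median exceeded that of the fast fibre and glycolysis genes by 0.48, which argues against fewer cells of other types acting alone. The slow fibre list had a median of 0.50, however, so fewer other cells together with a different fibre mix stay open. The slow minus fast score differed by 0.584 (exact permutation p = 0.143, adjusted p = 0.232). With it as a covariate, 1525 of 1850 called genes outside the fibre lists stayed called, and their median change went from 0.63 to 0.59. These values are not for the oxidative phosphorylation genes alone and do not cover other cells. Dependence on single T0 libraries stays open, since the count of 45 was 17 without T0 library m13, 22 without T0 library m9 and 26 without T0 library m10. Training, racing and the difference in age may each contribute and were not separated by the design.

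Several values stood apart from the rest of their time point by Dixon's test, and chance sets apart about 1 in 20 groups: 33 of 381 groups tested and 29 of 342 groups of named genes met it, 11 of the latter in T1 library m3. In T1 library m3 the slow minus fast score was 3.36 (next 0.13) and the mean log2 CPM of endothelial markers 3.95 (next 4.33). The log2 CPM of m3 was highest for MYL3 at 12.64, CHRNA1 at 5.80, CKM at 15.29, PSMB2 at 5.93 and ETFA at 8.24. It was lowest for MYH2 (ENSECAG00000024667) at 8.19, FAM69A at -0.01, MYL1 at 7.96, CD93 at 2.87, ACACA at 2.11 and CLOCK at 1.31.

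In T1 library m6 the log2 CPM was highest for SDC4 at 5.87, ANKRD1 at 10.78, XIRP1 at 11.04, ATF3 at 8.03 and BTG2 at 7.54. T1 library m11 was lowest for DHRS7C at 6.96, TUBB4A at 1.14 and VEGFB at 5.09. T1 library m4 was lowest for the mean of macrophage markers at 0.267, for CSF1R at -0.26 and for CIART at 2.63. T1 library m1 was lowest for ACADS at 5.57, and T1 library m2 highest for RNF213 at 3.97. Among T2 libraries, m23 was lowest for macrophage markers at -0.037 and highest for ANKRD2 at 7.20, m15 highest for ARNT at 4.42 and m17 lowest for ACOT11 at 0.11. Among T0 libraries, m12 was highest for PDK4 at 5.35, m13 highest for TEF at 4.49 and m9 lowest for PSMA3 at 5.22.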

How the results depend on the processing

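The alternatives without libraries m3 and m12, with the slow minus fast score, with the gene span trend removed and with thinned counts were chosen after seeing the data. Of the named calls, 26 of 39 in T1 minus T0, 47 of 58 in T2 minus T1 and 25 of 46 in T2 minus T0 were made whichever library was left out, and 28, 49 and 33 under each change of scaling, filter, test, covariate or fit that was not chosen after seeing the data. No list moved with an estimated correlation (0, 0 and 0 of 12, 7 and 10 by camera). Limma voom with sample weights gave 1512 genes for T1 minus T0 and 2940 for T2 minus T0, and leaving out libraries m3 and m12 gave 2947 for T2 minus T0. Leaving out 1 library gave 346 (without T0 library m10) to 904 genes for T1 minus T0, 2665 to 3775 for T2 minus T1 and 986 (without T0 library m13) to 2414 for T2 minus T0, with 10 to 14, 6 to 8 and 8 to 11 lists. With the slow minus fast score as a covariate 1 gene was called for T1 minus T0, though the score separates T1 from T0 completely. In that fit MYOZ2 had a T1 minus T0 log2 fold change of -0.03, PPP3CA of 0.00, LDHA of 0.11 and ACTN3 of 0.04 (MYOZ2 and ACTN3 are members of the score's lists), and BDH1 a T2 minus T1 log2 fold change of 0.01. BTG2 in T2 minus T1 was 0.03 in DESeq2, and -3.20 (without T2 library m15) to 0.01 (without T1 library m6) when 1 library was left out. DESeq2 called 1 gene between the sexes and 3 and 4 interactions, where edgeR called 0. Apart from fewer libraries in the left-out fits, the cause was not tested. Thinning to the smallest library left 657, 2946 and 1644 calls.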

Other observations

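The test of the sex labels was chosen only after the result was seen, whereas the random regroupings were not.

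Many lists showed few calls between T1 and T0 in edgeR. No member passed among 15 immediate early, 25 angiogenesis, 12 inflammation, 33 proteasome, 52 ribosomal protein, 12 endothelial and 5 macrophage genes. Exercise regulators rose in 3 and fell in 2 of 27 (4 and 2 when adjusted over the list alone), calcium handling genes rose in 3 and fell in 3 of 30 (4 and 5), and the 22 growth and atrophy genes gave 0 calls (1 and 1). Without T0 library m9 or m10, 1 exercise regulator rose, and 5 did in limma voom with sample weights. For the calcium list, 1 rose without T1 library m2 or m11 or T0 library m8, m10 or m13, and 0 fell without T0 library m10 or m13, 1 without T1 library m11 and 5 without T0 library m8 or T2 library m17. With only the 2 time points in the fit 1 calcium gene rose and 1 fell, and 5 fell in DESeq2, in limma voom with sample weights or with 1 surrogate variable. Myogenic genes rose in 1 of 16 (4 and 2 when adjusted over the list alone), clock genes in 1 of 17 (1 when adjusted over the list alone), adipocyte markers rose in 1 and fell in 1 of 9 (1 and 3), and smooth muscle markers rose in 0 and fell in 1 of 11 (1 and 3). The growth and atrophy list had a median log2 fold change of 0.15 and a mean of -0.02.

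Between T2 and T1, heat shock genes rose in 2 and fell in 2 of 22 (0 and 0 when adjusted over the list alone), extracellular matrix genes rose in 1 and fell in 2 of 42, and inflammation genes rose in 2 and fell in 1 of 12. Adipocyte markers rose in 1 and fell in 2 of 9, smooth muscle markers rose in 2 and fell in 2 of 11, and 1 of 12 endothelial and 1 of 5 macrophage markers fell (0 and 0 when adjusted over the list alone). None of 52 ribosomal protein and 10 fibroblast marker genes passed. Between T2 and T0, exercise regulators fell in 5 of 27 (2 without T0 library m9, 1 without T0 library m13, 2 without the filter or with only the 2 time points in the fit, and 3 with the trend on gene span removed), fatty acid genes rose in 4 of 25 (0 to 8 when 1 library was left out, 2 with 1 surrogate variable and 11 in limma voom with sample weights), growth and atrophy genes fell in 2 of 22, calcium handling genes fell in 2 of 30, inflammation genes fell in 2 of 12 (1 rose and 3 fell when adjusted over the list alone), and angiogenesis genes rose in 2 and fell in 2 of 25 (3 and 6). Of 12 endothelial markers 1 fell and of 10 fibroblast markers 1 fell. Neutrophil, lymphocyte and erythroid markers had 0 tested members, and the 4 Schwann cell, 1 skin and 2 tendon genes were too few for camera.

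Regrouping the libraries at random treats them as independent, although the labels do not say whether a horse was sampled more than once. By that test chance is unlikely to account for the gene counts, since 1 of 100 splits, the real one, gave as many genes in each comparison. The counts were 798 against at most 118 in the others for T1 minus T0, 3188 against 1390 for T2 minus T1 and 1851 against 7 for T2 minus T0. The same held for transcripts, where 1 of 100 splits reached 614 (highest other 18), 2948 (1153) and 1525 (8). Chance could not be excluded for the number of lists moved in camera, where 29, 70 and 31 of 100 splits gave as many as 12, 7 and 10, with a highest other of 16, 17 and 17. For the sexes the regroupings tested nothing, since with 0 genes and 0 T2 minus T1 interactions called all 100 splits give at least as many (highest other 189 and 5).

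Sex labels that do not match the libraries could have hidden a sex difference. The mean of 5 genes known to escape X inactivation was higher in females by 0.352 on the log2 scale (two-sided exact permutation within time points, p = 0.000345, 7 of 9 females and 2 of 14 males above their time point mean). All 5 were lower in males, from a log2 difference of -0.10 for UBA1 to -0.65 for DDX3X. The 5 were chosen after the sexes had been compared, and KDM6A and DDX3X were among the genes with the smallest p there, so the permutation p is not an independent test. With that limit, the values argue against labels out of place throughout, though not against a single wrong label. OFD1, an X-linked gene outside these 5, went the other way. It had 13.6 CPM in males and 8.51 CPM in females, a log2 difference of 0.68 ± 0.16 (SE, edgeR adjusted p = 0.373).

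The other pairs of comparisons also shared a time point. For T1 minus T0 and T2 minus T0, 82 genes were higher and 77 lower in both, against 27.7 and 35.9 for independent lists. With T0 divided between them, the medians were 1 and 2, against 0.259 and 2.04 for independent lists, counts too small to read. The Pearson r of the fold changes was 0.506, below the 0.65 of simulations of unchanged groups, while their covariance was 0.1327, against 0.0539. Genes were independent of each other in these simulations too, which limits them as a reference. For T2 minus T1 and T2 minus T0, 397 were higher and 638 lower in both, against 97.6 and 162 for independent lists. Simulations of unchanged groups shared 0 genes in each pair, which is no reference for these counts. With T2 divided, the medians were 66 and 191, against 9.79 and 26.4 for independent lists.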
